A study of Mus musculus with 14 samples.

How the data were processed

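RNA was measured on 14 single-colour Illumina mouse BeadChip arrays (Cy3 label), each hybridised with RNA from cells sorted from the mammary glands of FVB/NJ mice. Cells lacking CD45, CD31 and TER119, which mark leukocytes, endothelium and erythroid cells, were divided by CD29 and CD24 into a CD29-high CD24-positive population enriched for mammary stem cells (MaSC-enriched) and a CD29-low CD24-positive luminal population. The labels give a sort purity above 90% and up to 250 ng of RNA. They describe 3 cell pools from virgin mice and 4 from mice at day 12.5 of pregnancy.

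The deposited table of non-normalized values held probe intensity in arbitrary units, summarised per array and neither background corrected nor scaled between arrays. The deposited table also held a detection p-value for each probe on each array, the rank of the probe among negative control probes, of which the steps imply 935. The deposited series matrix held log2 values that were background corrected and quantile normalized, judged from the values themselves. The labels name BeadStudio and limma as the authors' tools and give no versions. Background correction with an offset of 50 followed by quantile normalization differed from the deposited log2 values by a median of 0.00477 and at most by 0.0719.

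Intensities were background corrected here by the normexp model of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16, then quantile normalized and taken to log2. Of 45281 probes, 20906 had a detection p below 0.05 in at least 3 arrays and were tested, which was 46.17% of them. A total of 10378 probes had no gene symbol in the reference used here, 18 had several, and 10 symbols were updated through the Entrez identifier. The 17804 tested probes with a single symbol covered 11349 genes, 4385 of them with several tested probes. A gene was represented by its tested probe with the highest mean over the 14 arrays. Arrays give no read depth, and their number limits the precision. Signal over background, the ratio of the 90th to the 10th percentile of raw intensity, ran from 7.44 to 16.3.

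Groups, comparisons, tests, gene lists, the choice of named genes and all alternatives except those for the correlation of pregnancy effects and the lists without part of their genes were set before the data were examined. A limma model with a mean for each of the 4 groups was fitted to the 14 arrays, with empirical Bayes moderation (10 residual and 4.74 prior degrees of freedom). All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all tested probes of a comparison, with a threshold of 0.05 and no minimum fold. The 5 comparisons were pregnant against virgin in each population, MaSC-enriched against luminal in each state, and the interaction, which is the pregnancy difference in MaSC-enriched cells minus that in luminal cells. Positive differences mean higher in pregnant or in MaSC-enriched cells. SE is the moderated standard error of a log2 difference, and SD is that of the arrays of a group.

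Gene lists covered basal, luminal and hormone-sensing luminal markers, milk and alveolar genes, lipid and sterol synthesis, proliferation, RANK and NF-kB signalling, paracrine mediators, Wnt, Notch, prolactin and STAT signalling, extracellular matrix and integrins, the secretory pathway and unfolded protein response, Myc and ribosome biogenesis, and the interferon response. Other lists covered fibroblast, adipocyte, leukocyte, endothelial, pericyte, erythroid, Schwann cell and skeletal muscle markers, dissociation stress, and housekeeping genes. The 23 lists with at least 3 tested genes were tested with limma's camera (preset inter-gene correlation of 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in a single direction and does not compare them with other genes. Luminal markers without the 4 genes shared with the hormone-sensing list, and milk genes without those with a group mean of log2 14 or more, were tested after the results were seen. Counts of list members past the threshold were made with p adjusted over all probes and with p adjusted over the list alone.

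Named genes were the 10 largest rises and 10 largest falls of each group comparison among genes past the threshold whose groups of arrays did not overlap, leaving out symbols of uncharacterised gene models. Added to these were the 5 largest of each direction in the interaction, up to 4 members of each list with the largest absolute difference, and a set of markers named whatever their values. Of that set, Prlr and Mki67 had no probe named for them here. Other genes were chosen after their values were seen: Aqp5, Plk1, Sfrp1 and Wnt7b in the account of pregnancy in MaSC-enriched cells, and the genes so described in the closing section. A fold to a group with no detected array is given as "at least", with each array of that group set to no less than the lowest normalized value called detected on that array. Where a group was detected on some of its arrays only, the fold rests partly on values near background.

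Alternatives were an offset of 50, no background correction, cyclic loess, scaling to the array median, the deposited log2 values, no filter, a stricter filter (detection p below 0.01 in every array of a group), chip as a fixed or random block, replicate number as a block, array weights, the compared groups alone, robust and trended moderation, a minimum fold of 1.5, and leaving out each array in turn. Scaling to the median shifted the median of all genes by -0.16 in the luminal pregnancy comparison and by 0.10 in the interaction, whereas the values used here had a shift of -0.10 in MaSC-enriched against luminal cells of pregnant mice. The labels do not say that equal replicate numbers in the populations are the same pool, and deviations from the group mean correlated best with the same number for all 3 virgin replicates but for none of the 4 pregnant ones, so pairing was left to the alternatives.

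The procedure was tested on simulated data with known changes in the same groups. In each simulated comparison 66 or 67 of 20906 probes were changed at each log2 size of 0.5, 1 and 2. Noise was independent between probes, with the same SD in every group. Real comparisons had more probes past the threshold and groups of unequal spread, so the shares below hold for the simulated setting only. At a log2 change of 2, between 83.3% and 92.4% of changed probes were recovered in the 4 group comparisons and 42.4% in the interaction. At a log2 change of 1, these shares were 20.9% to 28.4% and 1.49%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.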

Results

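Transcript levels of 11349 genes were measured in MaSC-enriched cells, which hold the basal and myoepithelial cells with the stem cell activity of the mammary gland, and in luminal cells, the ductal and alveolar epithelium. There were 3 arrays of each population from virgin mice and 4 of each from mice at day 12.5 of pregnancy, when alveoli form. The share of probes detected per array was 37.4% to 42.3% in virgin MaSC-enriched, 38.1% to 40.6% in pregnant MaSC-enriched, 38.7% to 40.0% in virgin luminal and 34.8% to 38.6% in pregnant luminal cells. Median raw intensity per array ran from 105 to 165 units. The arrays sat on 4 chips. Chip 1 held virgin luminal replicate 1, virgin MaSC-enriched replicate 1 and pregnant luminal replicates 1 and 2. Chip 2 held virgin MaSC-enriched replicate 2 alone. Chip 3 held virgin luminal replicate 2, pregnant luminal replicate 3 and pregnant MaSC-enriched replicates 1 to 3, and chip 4 held the remaining array of each group. Virgin MaSC-enriched arrays varied most, with a median SD of 0.44 on the log2 scale and correlations within the group of 0.917 to 0.934, against an SD of 0.24 and correlations of 0.98 to 0.985 in pregnant MaSC-enriched arrays.

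The first comparison asked how pregnancy changes the MaSC-enriched population. Milk and alveolar genes rose, with 12 of 18 past the threshold. Wap, a whey protein of milk, was 66.3-fold higher in pregnant cells (log2 13.37 ± 0.45, SD, n = 4) than in virgin cells (7.32 ± 0.82, n = 3), a log2 difference of 6.05 (SE 0.52, adjusted p = 2.33e-05 by limma). Fabp3, a fatty acid carrier, rose 33.6-fold, Cited4, a transcriptional coactivator, 16.7-fold, and Elf5, the transcription factor that directs alveolar differentiation, 10.8-fold (log2 3.44, SE 0.44, adjusted p = 0.000346). Among the largest falls was that of Lgr5, a Wnt pathway receptor used as a stem cell marker in several epithelia. It was detected on 1 of 4 pregnant arrays (log2 5.67 ± 0.40 against 10.11 ± 0.58, difference -4.44, SE 0.27, adjusted p = 1.28e-06). Slpi, a secreted protease inhibitor, was 28.3-fold lower (log2 -4.82, SE 0.36, adjusted p = 7.86e-06). The thioesterase Them5 was 23.1-fold lower, the serpin Serpinb11 10.3-fold lower, and the keratin Krt42 9.91-fold lower.

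Of 18 milk and alveolar genes measured in the MaSC-enriched population, 12 rose, Aqp5 fell (log2 -1.52) and 5 did not pass, and adjusted over the list alone 13 rose and 1 fell. The casein Csn2 rose 6.89-fold (log2 14.47 against 11.69, SE 0.31, adjusted p = 0.000122), and Wfdc18 rose by a log2 of 3.55, or 4.13 without virgin MaSC-enriched replicate 3. Glycam1 was higher by a log2 of 4.59 (adjusted p = 0.0155), a call that ended without virgin MaSC-enriched replicate 3 (adjusted p = 0.0501). The list median was 1.97 (camera adjusted p = 3.52e-11, and adjusted p = 0.0481 with an estimated correlation), with 2.04 when chip was a block and 1.45 within chip 4, the only chip with MaSC-enriched arrays of both states. Without 9 genes near the top of the scale in some group, the median was 1.88 (adjusted p = 0.000673, and adjusted p = 0.401 with an estimated correlation). Thrsp and Lpin1, which promote lipogenesis and triglyceride synthesis, rose by 3.95 (4.62 without virgin MaSC-enriched replicate 2) and 1.96. They were the 2 of 17 lipid synthesis genes that passed, and the list was not called (median 0.28, adjusted p = 0.0985). Without pregnant MaSC-enriched replicate 2 (median 0.28, adjusted p = 0.0246) or virgin MaSC-enriched replicate 3 (median 0.43, adjusted p = 0.0346) the lipid list was called.

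Of 23 proliferation genes, 5 rose in pregnant MaSC-enriched cells and none fell, and adjusted over the list alone 10 rose. They were the mitotic genes Cdk1 (log2 1.74), Aurka (1.71), Bub1b (1.65), Kif11 (1.62) and Plk1 (1.5). Array weights ended the first 4 of these calls (adjusted p = 0.087, 0.0595, 0.0752 and 0.184), and chip as a block ended those of Cdk1, Bub1b and Kif11 (adjusted p = 0.0957, 0.107 and 0.195). The Kif11 call also ended without virgin MaSC-enriched replicate 2 (adjusted p = 0.0675) or 3 (0.156), any pregnant MaSC-enriched replicate (0.0618 to 0.129), pregnant luminal replicate 1 (0.0588) or 2 (0.0632), or virgin luminal replicate 3 (0.0538). The list median of 0.85 (adjusted p = 8.05e-07, and adjusted p = 0.401 with an estimated correlation) became 0.37 with chip as a block, where the call ended (adjusted p = 0.162), and was 0.97 within chip 4. Leukocyte markers were higher beside them, with 1 of 8 past the threshold, and adjusted over the list alone 2. The T cell gene Cd3e was higher by a log2 of 1.56, and the list median was 0.70 (adjusted p = 0.0237, and adjusted p = 0.401 with an estimated correlation). The Cd3e call ended without any of pregnant MaSC-enriched replicates 2, 3 and 4 (adjusted p = 0.0627, 0.0555 and 0.0709). The leukocyte call ended with chip as a block (median 0.71, adjusted p = 0.0518), with the stricter filter (adjusted p = 0.0737), without virgin MaSC-enriched replicate 1 (adjusted p = 0.174) and without pregnant MaSC-enriched replicate 1 (adjusted p = 0.0618), and the median within chip 4 was 0.93.

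Basal identity genes showed no change that passed in the MaSC-enriched population, with 0 of 17 past limma's threshold both over all probes and adjusted over the list alone, 0 with an unadjusted p below 0.05, and a median of 0.20 (adjusted p = 0.542). The basal keratins Krt5 and Krt14 and the basal transcription factor Trp63 differed by log2 -0.49, 0.10 and 0.58. Krt14 was near the top of the scale (log2 14.36 in pregnant cells), where differences may be compressed. The luminal keratins Krt8 and Krt18 differed by 0.24 and 0.02. The Krt5 value rested on virgin MaSC-enriched replicate 3, where it was at 9.77 against 12.54 and 12.45 on the others, and without that array Krt5 fell by 1.40 (adjusted p = 0.00192). The sort markers Cd24a and Itgb1 differed by 0.60 and -0.05 and did not pass. General luminal markers were not called (median 0.02), with 2 of 19 higher and 2 lower, and 5 and 3 adjusted over the list alone. Of 22 Wnt signalling genes, 3 rose and 4 fell, and adjusted over the list alone 4 rose and 7 fell. The falls included the Wnt inhibitor Nkd2 (log2 -1.82), the secreted antagonist Sfrp1 (-1.43) and the ligand Wnt7b, which no pregnant array detected, while Rspo1, a secreted ligand that strengthens Wnt signals, was at least 4.36-fold higher. The list median of 0.08 and its mean of -0.21 differed in sign, and the list was not called. Tnfrsf11a, the receptor RANK, rose 2.61-fold (log2 1.38, SE 0.26, adjusted p = 0.00661), the single riser among 14 RANK and NF-kB genes (list median 0.05), a call that ended with median scaling (adjusted p = 0.0646) and array weights (0.0631). Its ligand Tnfsf11 differed by 0.08 (adjusted p = 0.932). The integrin Itgb4 of hemidesmosomes fell 3.87-fold (log2 -1.95, adjusted p = 6.02e-05), the growth inhibitor Tgfb1 fell by 1.57, and the basement membrane chain Lama1 rose by 1.37. The extracellular matrix list had 1 rise and 2 falls among 22 genes and was not called, except with chip as a block (median -0.33, adjusted p = 0.0247).

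Of 10 hormone-sensing luminal markers, 2 fell and none rose in pregnant MaSC-enriched cells, and adjusted over the list alone 3 fell. These were the pioneer factor Foxa1 (at least 3.51-fold lower) and the coregulator Cited1 (at least 1.82-fold lower), and both calls ended with chip as a block (adjusted p = 0.0665 and 0.0653) and with no background correction (0.0875 and 0.11). The list median of -0.53 (adjusted p = 0.0237, and adjusted p = 0.361 with an estimated correlation) became -0.13 with chip as a block (adjusted p = 0.439) and was -0.31 within chip 4. The call also ended with no background correction (median -0.32, adjusted p = 0.0626), cyclic loess (adjusted p = 0.0556), median scaling (adjusted p = 0.0975) and the stricter filter (adjusted p = 0.0701), and without virgin MaSC-enriched replicate 1 (adjusted p = 0.0734) or 2 (adjusted p = 0.104). None of 10 Myc and ribosome biogenesis genes passed by limma, either over all probes or adjusted over the list alone, 4 had an unadjusted p below 0.05, and the median was -0.50 (adjusted p = 0.0237, and adjusted p = 0.401 with an estimated correlation), -0.76 with chip as a block and -0.66 within chip 4. The ribosome call ended with the stricter filter (adjusted p = 0.0701) and without virgin MaSC-enriched replicate 1 (adjusted p = 0.179) or 3 (adjusted p = 0.0697).

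Across the MaSC-enriched population, 943 of 20906 probes passed, 526 higher and 417 lower in pregnancy, representing 321 genes higher and 262 lower. Median scaling turned the balance, to 250 higher and 381 lower. Groups of arrays did not overlap for 16.5% of genes, against 5.71% by chance. Among genes that passed, 99.8% had the same direction within chip 4, whose arrays are part of the fit, and 1306 probes passed with chip as a block. Without virgin MaSC-enriched replicate 2, which was alone on its chip, 2011 probes passed, and without pregnant MaSC-enriched replicate 2 there were 497. The MaSC-enriched arrays of both states shared a chip only on chip 4, so the blocked values also drew on luminal arrays to set the chip differences. They could depart from the chip 4 pair, with proliferation medians of 0.37 blocked and 0.97 within chip 4, and fibroblast medians of -0.34 and 0.73.

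**Figure D1:**
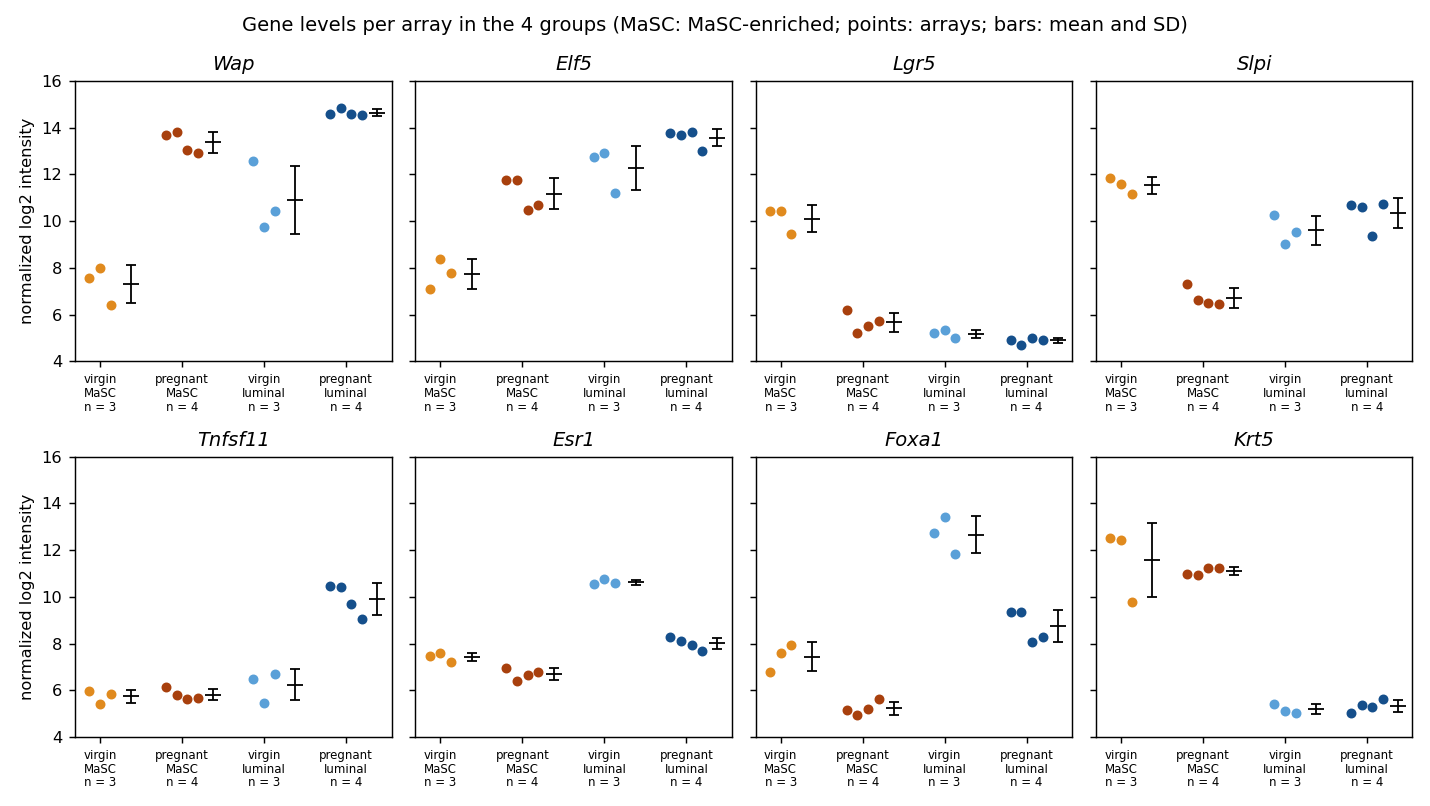
Normalized log2 intensity of 8 genes on every array (points) with the group mean and SD (bars), for virgin (n = 3) and pregnant (n = 4) MaSC-enriched and luminal cells. Lgr5 was at 10.11 in virgin MaSC-enriched cells and at 5.67 in pregnant ones, and Tnfsf11 at 6.23 in virgin luminal cells and 9.91 in pregnant ones.

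The second comparison asked how pregnancy changes the luminal population, where more probes passed. Gldc, a glycine cleavage enzyme detected on 1 of 3 virgin luminal arrays, rose in pregnancy (log2 12.01 ± 0.15, SD, n = 4, against 6.06 ± 0.81, n = 3, difference 5.95, SE 0.31, adjusted p = 8.71e-09 by limma). Thrsp rose 46.1-fold, or by a log2 of 6.11 in place of 5.53 without virgin luminal replicate 1. The growth factor Igf2 rose 28.6-fold, or by a log2 of 4.09 in place of 4.84 without virgin luminal replicate 2. Pigr, the carrier of antibodies into milk, rose 21.3-fold (adjusted p = 3.43e-06). Ido1, a tryptophan-degrading enzyme, was at least 147-fold lower (log2 4.79 against 13.02, SE 0.35, adjusted p = 4.11e-09) and below detection on every pregnant luminal array. The surface antigen Ly6d, the collagen Col8a1 and the cytokine Il33 fell from log2 13.72, 12.55 and 11.95 to values near background, 6.27, 5.86 and 5.69. They were detected on 3, 3 and 1 of the 4 pregnant luminal arrays.

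Of 10 hormone-sensing luminal markers, 6 fell and 1, a paracrine ligand, rose in pregnant luminal cells, and adjusted over the list alone 7 fell and 1 rose. The list median was -2.34 and its mean -1.48 (adjusted p = 0.000248, and adjusted p = 0.0918 with an estimated correlation). The oestrogen receptor gene Esr1 fell 6.16-fold (log2 8.01 ± 0.25 against 10.63 ± 0.11, difference -2.62, SE 0.20, adjusted p = 3.54e-07). The progesterone receptor gene Pgr was at least 4.81-fold lower (log2 -2.85, or -2.25 without virgin luminal replicate 1). Foxa1 fell 15-fold, Cited1 10.9-fold and the T-box factor Tbx3 9.73-fold. Tnfsf11, the RANK ligand through which hormone-sensing cells signal to their neighbours, rose 12.8-fold (log2 9.91 ± 0.67 against 6.23 ± 0.66, difference 3.68, SE 0.35, adjusted p = 3.19e-06). Wnt4, another progesterone-driven ligand, differed by log2 -0.84 (adjusted p = 0.0547) and passed with chip as a block (adjusted p = 0.0223) and median scaling (adjusted p = 0.00858). The list median was -2.38 with chip as a block and -2.42, -2.21 and -2.12 within chips 1, 3 and 4.

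Ligands and receptors changed in both directions in the luminal population. The receptor Tnfrsf11a rose 3.98-fold (log2 1.99, SE 0.26, adjusted p = 6.4e-05), and 3 of 14 RANK and NF-kB genes rose with none falling, a list that was not called (median 0.10). Among 14 paracrine mediators, 4 rose and 3 fell, and adjusted over the list alone 4 fell. Wnt5a fell 29.7-fold (adjusted p = 6.37e-07), and Inhba, an activin subunit, was at least 9.76-fold lower. The median of these mediators was -0.08 and the mean 0.22, with no call. Of 22 Wnt signalling genes, 6 rose and 2 fell, and adjusted over the list alone 6 rose and 3 fell. Wnt7b was at least 21.5-fold lower (adjusted p = 3.35e-08), Rspo1 rose 12.4-fold and the Wnt repressor Tcf7l1 5.27-fold. The log2 rise of Rspo1 was 3.63, with 2.96 without virgin luminal replicate 2 and 4.38 without replicate 3. The Notch target Hey1 fell 38.9-fold (log2 -5.28, or -5.99 without virgin luminal replicate 3) and the Notch ligand Jag1 by 1.60, which made 2 falls among 13 Notch genes and, adjusted over the list alone, 5. The interferon target Usp18 fell 10.6-fold, with Oasl2 (log2 -1.55) and Stat2 (-1.18), which were 3 falls among 12 interferon genes (median -0.33, adjusted p = 0.0699). Without virgin luminal replicate 3 the interferon list was called lower (median -0.45, adjusted p = 0.0258).

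Of 17 lipid synthesis genes, 12 rose in pregnant luminal cells and Dgat2, which makes triglyceride, fell 17.7-fold (adjusted p = 2.33e-07), and adjusted over the list alone 13 rose and 1 fell. Fatty acid synthase, Fasn, rose 3.69-fold and Lpin1 3.85-fold. The lipid list median was 1.08 (adjusted p = 0.000217, and adjusted p = 0.102 with an estimated correlation), with 1.13 with chip as a block and 0.83, 1.32 and 1.34 within chips 1, 3 and 4. Of 23 proliferation genes, 12 rose and none fell, and adjusted over the list alone 18 rose. The mitotic checkpoint gene Bub1b rose 4.18-fold, the mitotic kinase Plk1 3.87-fold and Birc5, which guides chromosome separation, 3.79-fold. Their list median was 1.14 (adjusted p = 1.09e-05, and adjusted p = 0.555 with an estimated correlation), with 1.11 with chip as a block and 1.68, 1.20 and 0.63 within the 3 chips.

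Of 18 milk genes, 6 rose in pregnant luminal cells and Aqp5 fell 17.1-fold. Adjusted over the list alone, 7 rose and 1 fell. Wap rose 13.2-fold (log2 14.65 against 10.93, difference 3.73, adjusted p = 0.000116), with 4.55 without virgin luminal replicate 1. Csn2 was at 14.31 and 14.41, near the top of the scale, and differed by -0.10 (adjusted p = 0.881). Elf5 differed by 1.29 (adjusted p = 0.0541) and passed with chip as a block (adjusted p = 0.0285). The milk list call depended on the processing. It was not called with the values used here (median 0.28, adjusted p = 0.0699). It was called with median scaling (median 0.53, adjusted p = 0.000198), cyclic loess (median 0.45, adjusted p = 0.0135), the mean of all probes of a gene (median 0.68, adjusted p = 0.0321) and fry (adjusted p = 0.0361). Leaving out virgin luminal replicate 1 (median 0.61, adjusted p = 0.00962) or pregnant luminal replicate 3 (median 0.35, adjusted p = 0.0461) also brought the call.

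Of 19 general luminal markers, 7 fell and 1 rose in pregnant luminal cells, and adjusted over the list alone 8 fell and 2 rose, with a median of -0.50 (adjusted p = 0.00201, and adjusted p = 0.555 with an estimated correlation). Of the 7, 4 were hormone-sensing markers too (Foxa1, Esr1, Pgr and Prom1), and without these the list was not called (median -0.46, adjusted p = 0.238). The keratin Krt7 fell 11.4-fold, while Krt8 and Krt18 differed by 0.45 and -0.46 and did not pass. The sort markers Cd24a and Itgb1 differed by -0.0039 and -0.28. The median was -0.47 with chip as a block and -0.44, -0.80 and -0.77 within chips 1, 3 and 4. Of 17 basal markers, 6 rose and none fell, and adjusted over the list alone 8 rose. Krt14 rose 5.09-fold (log2 2.35, or 1.52 without virgin luminal replicate 2), and the smooth muscle genes Actg2 and Myh11 rose by log2 2.40 and 1.93, or 3.45 and 2.69 without virgin luminal replicate 1. Krt5 was detected in neither state, and Trp63 differed by 1.29 (adjusted p = 0.078, with 0.0354 with chip as a block). The basal median was 0.50 (adjusted p = 0.0234, and adjusted p = 0.555 with an estimated correlation). The call ended with chip as a block (median 0.55, adjusted p = 0.0522), array weights (median 0.30, adjusted p = 0.691) and the mean of all probes of a gene (median 0.30, adjusted p = 0.0594), and without virgin luminal replicate 2 (median 0.40, adjusted p = 0.114). Within chips 1, 3 and 4 it was 0.10, 1.38 and 0.81.

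Leukocyte markers had a median of 0.80 in the luminal pregnancy comparison (adjusted p = 0.0267, and adjusted p = 0.555 with an estimated correlation), with 2 of 8 past the threshold. The antigen presentation gene Cd74 rose 3.57-fold (adjusted p = 0.00455) and Cd52 by a log2 of 1.22, also when adjusted over the list alone. The leukocyte median was 0.84 with chip as a block and 0.10, 1.35 and 1.47 within chips 1, 3 and 4. The list call ended with no background correction (median 0.46, adjusted p = 0.0503), the stricter filter (adjusted p = 0.133) and array weights (median 0.30, adjusted p = 0.238). It also ended without virgin luminal replicate 2 (adjusted p = 0.0643), virgin luminal replicate 3 (0.0529) or pregnant luminal replicate 4 (0.0788). The Cd52 call ended without virgin luminal replicate 2 (adjusted p = 0.142), virgin luminal replicate 3 (0.151), pregnant luminal replicate 3 (0.0694) or pregnant luminal replicate 4 (0.101), and with chip as a block (0.0528).

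Across the luminal population, 4087 probes passed, 2035 higher and 2052 lower in pregnancy, representing 1237 genes higher and 1232 lower. This even balance depended on the scaling, with 795 higher and 2327 lower by median scaling and 1649 higher and 2304 lower by cyclic loess. Groups of arrays did not overlap for 33.8% of genes, against 5.71% by chance. Of the genes that passed, 99.8%, 99.8% and 99.1% had the same direction within chips 1, 3 and 4, whose arrays are part of the fit. A total of 5098 probes passed with chip as a block. With array weights, which gave virgin luminal replicate 1 a weight of 5.89, 9271 probes passed.

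**Figure D2:**
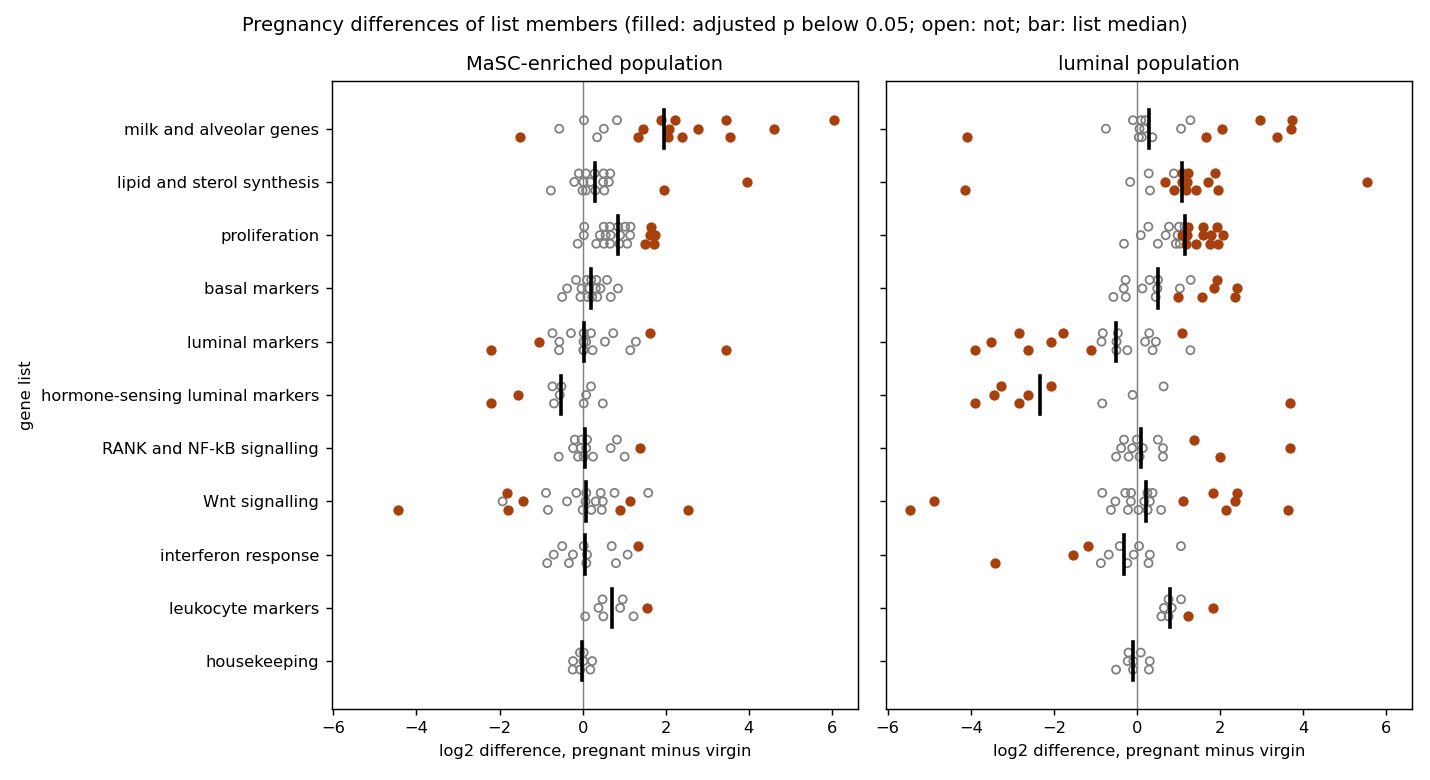
Log2 difference between pregnant and virgin cells (horizontal axis) of each measured member of 11 gene lists (vertical axis) in MaSC-enriched and luminal cells, filled where the adjusted p was below 0.05, with bars at list medians. Milk genes had a median of 1.97 in MaSC-enriched and 0.28 in luminal cells, and hormone-sensing markers -0.53 and -2.34.

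The third comparison asked what set the populations apart in virgin mice. Basal cell genes were higher and luminal genes lower in MaSC-enriched than in luminal cells. The basal transcription factor Trp63 was 100-fold higher (log2 6.65, SE 0.52, adjusted p = 1.32e-07 by limma, n = 3 and 3), the hemidesmosome collagen Col17a1 86.5-fold higher, and the basal cadherin Cdh3, detected on 1 of 3 luminal arrays, higher by a log2 of 6.49 (SE 0.24, adjusted p = 5.46e-10). The chemokine Cxcl14, although a member of the hormone-sensing luminal list, was 115-fold higher. Aqp5, a water channel, was 45.5-fold lower (log2 -5.51, adjusted p = 4.49e-09), Cited1 42.9-fold lower and Foxa1 37.4-fold lower (log2 -5.22, SE 0.44, adjusted p = 2.71e-07). Of the markers used for the sort, the integrin Itgb1, which is CD29, was 2.18-fold higher (adjusted p = 0.00726, or 0.0804 with only these groups in the fit), and Cd24a 3.63-fold lower (adjusted p = 0.000637).

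All 17 basal markers measured were higher in virgin MaSC-enriched cells, also when adjusted over the list alone, with a median of 4.87 (adjusted p = 3.2e-15, and adjusted p = 0.0338 with an estimated correlation). Krt5 was at least 62.2-fold higher, and its log2 difference of 6.40 became 7.31 without virgin MaSC-enriched replicate 3. Krt14 was 7.42-fold higher (log2 2.89, or 2.06 without virgin luminal replicate 2). Of 19 luminal markers, 18 were lower, and 19 when adjusted over the list alone, with a median of -3.20 (adjusted p = 5.62e-14, and adjusted p = 0.0429 with an estimated correlation). Krt18 was 8.59-fold lower, Elf5 23.3-fold lower and the tight junction gene Cldn3 21-fold lower, whereas Krt8 differed by -0.58 (adjusted p = 0.0532, with 0.0214 without background correction). Of 10 hormone-sensing markers, 7 were lower and 1, Cxcl14, higher, and adjusted over the list alone 7 were lower and 2 higher. Esr1 was 9.20-fold lower, Wnt4 16.1-fold lower, and Pgr at least 5.53-fold lower (log2 -2.87, or -2.28 without virgin luminal replicate 1), with a list median of -2.48 (adjusted p = 0.00176, and adjusted p = 0.0454 with an estimated correlation). These medians with chip as a block were 5.2, -3 and -2.43. Within chips 1 and 4 they were 3.82 and 4.75 for basal, -3.57 and -2.53 for luminal, and -2.77 and -2.20 for hormone-sensing markers.

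Milk genes were lower in virgin MaSC-enriched than in luminal cells, with 15 of 18 past the threshold both over all probes and adjusted over the list alone, and a median of -2.82 (adjusted p = 1.19e-08, and adjusted p = 0.0429 with an estimated correlation). Csn2 was 6.60-fold lower, and Wap 12.1-fold lower (log2 -3.60, or -2.78 without virgin luminal replicate 1). Of 22 Wnt genes, 11 were higher and 5 lower, with Lgr5 at least 22.3-fold higher (adjusted p = 8.03e-09), Nkd2 at least 18.5-fold higher and Dkk3, a Dickkopf family member, 46.9-fold higher, and a median of 1.09 (adjusted p = 0.00518, and adjusted p = 0.0454 with an estimated correlation). Of 22 matrix genes, 10 were higher, and 12 when adjusted over the list alone, among them the basement membrane chains Lama1 (39.1-fold) and Col4a2 (29-fold), with a median of 1.06 (adjusted p = 7.7e-06, and adjusted p = 0.0567 with an estimated correlation). With chip as a block the milk, Wnt and matrix medians were -2.69, 1.15 and 1.60. Within chips 1 and 4 they were -3.57 and -2.24, 1.26 and 1.41, and 1.99 and 1.44.

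Myc and ribosome biogenesis genes were higher in virgin MaSC-enriched cells, with 5 of 10 past the threshold, also when adjusted over the list alone, and a median of 0.69 (adjusted p = 0.0499, and adjusted p = 0.489 with an estimated correlation). With chip as a block the median was 0.90 (adjusted p = 0.0104), and within chips 1 and 4 it was 0.86 and 0.77. The call ended with the stricter filter (adjusted p = 0.0726) and without virgin MaSC-enriched replicates 1 and 3 (adjusted p = 0.0988 and 0.0931), virgin luminal replicate 2 (0.1), pregnant luminal replicate 2 (0.0501), and pregnant MaSC-enriched replicates 2, 3 and 4 (0.0501, 0.0514 and 0.0538). The pericyte gene Rgs5 was 8.34-fold higher and the fibroblast gene Fbln1 13.7-fold higher in MaSC-enriched cells (log2 3.77, or 4.45 without virgin luminal replicate 2). Neither cell type's list was called, with a pericyte median of 1.28 (adjusted p = 0.0696) and a fibroblast median of 0.74 (adjusted p = 0.0764). Both were called with chip as a block (adjusted p = 0.043 and 0.0289), with array weights (adjusted p = 0.0457 and 0.046) and without virgin MaSC-enriched replicate 3 (adjusted p = 0.00924 and 0.0319). Median scaling brought the pericyte call (adjusted p = 0.0454). The fibroblast list was also called without virgin luminal replicate 2 (adjusted p = 0.00712), and the endothelial list (median 1.27) without virgin MaSC-enriched replicate 1 (adjusted p = 0.015). Proliferation genes were called higher with chip as a block (median 0.52, adjusted p = 0.0408) and array weights (median 0.88, adjusted p = 0.0081). Their median differed between chips, at 1.42 within chip 1 and -0.10 within chip 4. Skeletal muscle genes had a median of -1.68 (adjusted p = 0.0731), and were called lower with chip as a block (adjusted p = 0.0465) and without virgin luminal replicate 3 (adjusted p = 0.0128).

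In virgin mice 6095 probes passed, 2852 higher and 3243 lower in MaSC-enriched cells, representing 1760 genes higher and 1888 lower. The balance turned with cyclic loess, to 3184 higher and 2817 lower. Groups of arrays did not overlap for 37.7% of genes, against 10% by chance. Of the genes that passed, 99.9% and 99.5% had the same direction within chips 1 and 4, whose arrays are part of the fit, and 6695 probes passed with chip as a block.

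The fourth comparison asked the same in pregnant mice. Snai2, a transcription factor of basal cells, was 62.6-fold higher in MaSC-enriched cells (log2 5.97, adjusted p = 8.87e-10 by limma, n = 4 and 4), the neurotrophin receptor Ntrk3 at least 55.9-fold higher (log2 6.42, SE 0.21, adjusted p = 4.33e-11) and Nrg1, a growth factor that basal cells supply to luminal cells, at least 42.9-fold higher. Tnfsf11 was 17-fold lower (log2 -4.09, SE 0.32, adjusted p = 1.06e-07), Esrrb, an orphan nuclear receptor, at least 20.2-fold lower, and Tph1, which makes serotonin, at least 15-fold lower (adjusted p = 2.22e-06). The difference of Wap was -1.28 (adjusted p = 0.0468), and with chip as a block it did not pass (-0.75, adjusted p = 0.2). The Wap call ended without any array of either pregnant group, with adjusted p from 0.0509 without pregnant MaSC-enriched replicate 2 to 0.116 without pregnant MaSC-enriched replicate 4. Without virgin MaSC-enriched replicate 1 and virgin luminal replicate 3, the adjusted p was 0.052 and 0.0502. Csn2 differed by 0.16 (adjusted p = 0.696). It was near the top of the scale in both populations (log2 14.47 and 14.31), as was Wap in luminal cells (14.65), where differences may be compressed.

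Of 17 basal markers, 15 were higher and none lower in pregnant MaSC-enriched cells, and adjusted over the list alone 16 were higher (median 4.74, adjusted p = 1.34e-11, and adjusted p = 0.083 with an estimated correlation). Trp63 was 61.4-fold higher and Krt5 at least 38.8-fold higher, while Krt14 differed by 0.65 (adjusted p = 0.226). Krt14 was near the top of the scale in MaSC-enriched cells (log2 14.36, with 13.72 in luminal cells), so its difference was compressed. Of 19 luminal markers, 16 were lower, and 17 when adjusted over the list alone (median -2.39, adjusted p = 5.28e-07, and adjusted p = 0.136 with an estimated correlation). The mucin Muc1 was 10.4-fold lower, Krt19 8.42-fold lower and Elf5 5.24-fold lower. The basal and luminal medians with chip as a block were 5.09 and -2.51. Within chips 3 and 4 they were 4.5 and 4.32, and -2.02 and -2.30. Hormone-sensing markers were not called (median -0.65), with 5 lower and 2 higher of 10. Esr1 was 2.48-fold lower and Wnt4 6.46-fold lower. Pgr differed by 0.17, but was detected on no pregnant luminal and 1 pregnant MaSC-enriched array, so its levels could not be compared. Itgb1 was 2.54-fold higher and Cd24a 2.38-fold lower, a call that ended with median scaling (adjusted p = 0.0541).

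Of 18 milk genes, 11 were lower in pregnant MaSC-enriched than in luminal cells, also when adjusted over the list alone, among them Lalba, which directs lactose synthesis (10.6-fold), and lactoferrin, Ltf (9.49-fold), with a median of -2.36 (adjusted p = 0.00142, and adjusted p = 0.232 with an estimated correlation). Of 17 lipid genes, 12 were lower and 1 higher, also when adjusted over the list alone, with Thrsp 8.91-fold lower and a median of -1.19 (adjusted p = 0.00142, and adjusted p = 0.136 with an estimated correlation). Of 22 Wnt genes, 12 were higher and 3 lower, and adjusted over the list alone 13 and 4, with Wnt6 at least 28.8-fold and the receptor Fzd7 13-fold higher and a median of 0.66 (adjusted p = 0.0109, and adjusted p = 0.136 with an estimated correlation). Of 22 matrix genes, 11 were higher and 2 lower, with the matrix protease Mmp2 12.4-fold higher and a median of 1.49 (adjusted p = 8.66e-05, and adjusted p = 0.136 with an estimated correlation). The milk, lipid, Wnt and matrix medians with chip as a block were -2.39, -1.32, 0.75 and 0.95. Within chips 3 and 4 they were -2.16 and -2.25, -1.45 and -1.33, 0.67 and 0.70, and 0.97 and 1.49.

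Fibroblast markers were higher beside the matrix genes, with 4 of 10 past the threshold, also when adjusted over the list alone, and a median of 1.38 (adjusted p = 0.0112, and adjusted p = 0.783 with an estimated correlation). The matrix proteoglycan Dcn was 5.84-fold and Fbln1 12.6-fold higher. The fibroblast call ended with chip as a block (median 0.68, adjusted p = 0.103), and within chips 3 and 4 the median was 0.11 and 0.80. Endothelial markers were not called (median 1.56, adjusted p = 0.104) with 6 of 7 higher, and were called without pregnant MaSC-enriched replicate 4 (median 1.81, adjusted p = 0.0387). The Notch ligand Dll1 was 51.8-fold and its relative Jag2 at least 14.7-fold higher in MaSC-enriched cells, and Myc 4.07-fold higher (adjusted p = 7.95e-05). Stat5a, which carries the prolactin signal, was 4.96-fold lower, and the STAT inhibitor Socs3 6.05-fold higher.

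In pregnant mice 8260 probes passed, 3796 higher and 4464 lower in MaSC-enriched cells, representing 2289 genes higher and 2615 lower. Which direction had more depended on the scaling, with 4280 higher and 3375 lower by cyclic loess and 3603 higher and 2876 lower by median scaling. Groups of arrays did not overlap for 50% of genes, against 2.86% by chance. Of the genes that passed, 99.9% and 99.4% had the same direction within chips 3 and 4, whose arrays are part of the fit, and 8300 probes passed with chip as a block. Of the genes higher in MaSC-enriched cells, 1358 passed in both states, against 355 if independent, and 1210 of those lower, against 435.

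The interaction asked which genes answered pregnancy differently in the populations. Of 994 genes that passed, 279 were below detection on every array of some group and 129 on every array of a population, and background sets part of their values. Tnfsf11 rose in luminal cells, with a difference of 0.08 in MaSC-enriched cells (interaction -3.59 on the log2 scale, SE 0.50, adjusted p = 0.000411 by limma over n = 14 arrays), and Igf2 rose in luminal cells, with -1.10 in MaSC-enriched cells (-5.94, SE 0.74, adjusted p = 0.00017, or -5.19 without virgin luminal replicate 2). Pcdha7, a clustered protocadherin, fell below detection in pregnant luminal cells and rose in MaSC-enriched cells (6.70, SE 0.51, adjusted p = 2.89e-06). Lgr5 fell in MaSC-enriched cells and was detected on no luminal array, and Ido1 was detected on no pregnant array of either population, so their responses could not be compared. For Tnfrsf11a, which rose in both populations, no difference was shown (-0.61, adjusted p = 0.371), nor for Wap (2.33, adjusted p = 0.07), although Wap passed with chip as a block (3.35, adjusted p = 0.0118).

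Of 18 milk genes, 7 had a higher pregnancy difference in MaSC-enriched than in luminal cells and none a lower one, and adjusted over the list alone 9 (median 1.14, adjusted p = 0.00285, and adjusted p = 0.344 with an estimated correlation). Of the 7, 5 were near the top of the scale in pregnant luminal cells, where a rise is compressed: Csn1s1, Csn2, Csn3, Wfdc18 and Trf. Without the genes near the top, 2 of 9 passed, Elf5 (2.15) and Aqp5 (2.57), and the list was not called (median 0.47, adjusted p = 0.421), so a differing response of milk genes was not shown. With chip as a block the milk median was 1.45, and within chip 4 it was 0.34. Of 10 hormone-sensing markers, 5 had a higher and Tnfsf11 a lower difference, and adjusted over the list alone 7 and 2 (median 1.79, adjusted p = 0.0111, and adjusted p = 0.344 with an estimated correlation), among them Esr1 (1.89, adjusted p = 0.000765) and Tbx3 (2.77). The other 3 of the 5 were at background in MaSC-enriched cells, with Prom1 detected on none of their arrays, Pgr on 1 of 7 and Cited1 on no pregnant one, so their falls could not be compared. The hormone-sensing median was 1.98 with chip as a block and 1.35 within chip 4. Of 19 luminal markers, 5 had a higher difference, and 8 adjusted over the list alone (median 0.94, adjusted p = 3.91e-05, and adjusted p = 0.344 with an estimated correlation). Of these 5, 3 were hormone-sensing markers, and without the 4 shared genes the median was 0.71 (adjusted p = 0.0111, and adjusted p = 0.537 with an estimated correlation). The whole list had 0.49 with chip as a block and 0.05 within chip 4. Of 22 Wnt genes, 2 had a higher difference, Wnt5a (4.96) and Wnt7b, which no pregnant array detected, and 7 a lower one, among them Dkk3 (-3.24), with no call (median -0.39).

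Lipid synthesis genes had, as a list, a lower pregnancy difference in MaSC-enriched than in luminal cells (median -0.55, adjusted p = 0.0236, and adjusted p = 0.344 with an estimated correlation). Of 17 lipid genes, 2 had a lower difference, Fasn (-1.58) and Dgat1 (-1.50), and 1 a higher one, Dgat2 (3.38), and adjusted over the list alone 6 and 1. The Fasn call ended with median scaling (adjusted p = 0.193) and without virgin MaSC-enriched replicate 1 (0.0556) or virgin luminal replicate 2 (0.0581). The lipid median was -0.85 with chip as a block and -0.96 within chip 4, and the call ended with array weights (adjusted p = 0.11) and without virgin luminal replicate 2 (adjusted p = 0.0591), virgin MaSC-enriched replicate 3 (0.0585) or virgin luminal replicate 3 (0.0654). Myc and ribosome genes had 1 lower difference of 10, and 5 adjusted over the list alone (median -1.02, adjusted p = 0.0153, and adjusted p = 0.375 with an estimated correlation). Their median was -1.18 with chip as a block and -0.80 within chip 4, and the call ended without virgin luminal replicate 2 (adjusted p = 0.0591). Interferon genes had 2 higher differences of 12, and 3 adjusted over the list alone, with Usp18 at 3.49 (median 0.91, adjusted p = 0.0486, and adjusted p = 0.427 with an estimated correlation). The interferon call ended with chip as a block (median 0.73, adjusted p = 0.0642), the stricter filter (0.0776), array weights (0.134) and the mean of all probes of a gene (0.0654). It also ended without any of virgin luminal replicate 2 (0.177), virgin MaSC-enriched replicate 3 (0.169), pregnant MaSC-enriched replicate 2 (0.0773), or pregnant luminal replicates 2, 3 and 4 (0.0541, 0.051 and 0.0607), and the median within chip 4 was 0.95. Of 5 skeletal muscle genes, 1 had a higher difference, Acta1 at 5.43, or 6.04 without virgin luminal replicate 3 (median 0.83, adjusted p = 0.0282, and adjusted p = 0.411 with an estimated correlation). The muscle median was 0.68 with chip as a block and 0.34 within chip 4, and the call ended with the stricter filter (adjusted p = 0.118) and without virgin luminal replicate 2 (adjusted p = 0.097) or virgin MaSC-enriched replicate 3 (0.0767).

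The basal list was not called in the interaction (median -0.56, adjusted p = 0.0687) and was called with median scaling (median -0.50, adjusted p = 0.0378) and without virgin luminal replicate 1 (median -0.74, adjusted p = 3.15e-05) or pregnant luminal replicate 1 (median -0.54, adjusted p = 0.0461). Chip as a block brought calls for proliferation (median -0.59, adjusted p = 0.0128), matrix genes (-0.83, adjusted p = 0.0306) and dissociation stress genes (0.53, adjusted p = 0.0128). Within chip 4 the proliferation median had the opposite sign (0.43), and the matrix and stress medians were -0.94 and 0.85. Array weights also brought the proliferation call (median -0.95, adjusted p = 0.00111). Leaving out virgin MaSC-enriched replicate 2 brought the proliferation (adjusted p = 0.0376) and stress (adjusted p = 0.0403) calls.

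In the interaction 1587 probes passed, 995 with a higher and 592 with a lower difference in MaSC-enriched cells, representing 609 and 385 genes. Among genes that passed, 99.9% had the same direction within chip 4, the only chip with all 4 groups, whose arrays are part of the fit, and 2121 probes passed with chip as a block. Without virgin MaSC-enriched replicate 2, 2645 probes passed, and with array weights 2700. Across genes, which are not independent replicates, the pregnancy differences in the populations correlated with r = 0.377 and rho = 0.312. Of the genes higher in pregnancy, 140 passed in both populations, against 35 if independent, and of those lower, 101 against 28.4.

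**Figure D3:**
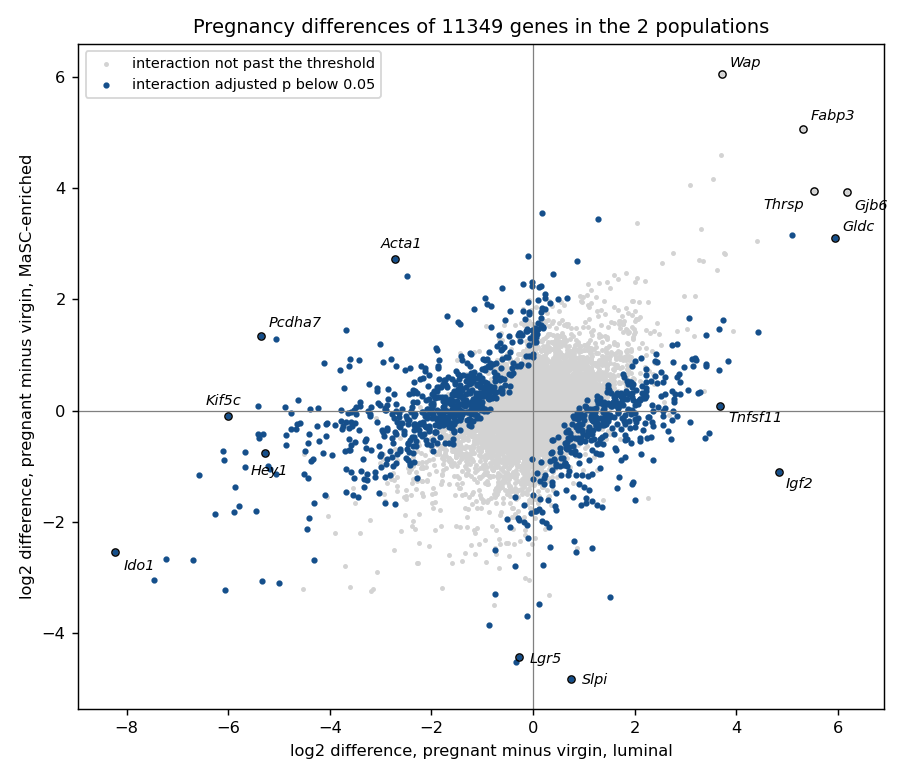
Log2 difference between pregnant and virgin cells in luminal (horizontal axis) and MaSC-enriched cells (vertical axis) for 11349 genes, blue where the interaction had an adjusted p below 0.05. Wap lies at 3.73 and 6.05, Lgr5 at -0.28 and -4.44, and Igf2 at 4.84 and -1.10.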

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

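The counts over regrouped arrays were planned before the data were examined, while the count with the common pregnancy difference taken out, the lists without part of their genes, and the tests of cell shares, of hormone-sensing members, of chip and of normalization below were chosen only after the results they concern were seen.

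The pregnancy difference was tested for a difference between the populations, and 1587 probes passed. Among single genes, Pcdha7 had an interaction of 6.70, Kif5c, a kinesin motor, 5.92, Ido1 5.68 and Piezo2, a mechanosensitive channel, 5.50, while Igf2 had -5.94, Slpi -5.56, Serpinb11 -4.88, Them5 -4.19 and Lgr5 -4.16. Of these, Ido1 was detected on no pregnant array, Lgr5 on no luminal array and Them5 on 1 of 7 luminal arrays, so background set part of their values and the size of a differing response was not measured. Pcdha7, Kif5c and Enho were detected on no pregnant luminal array and Piezo2 on 2 of 4 and on 2 of 3 virgin MaSC-enriched ones. Serpinb11 was detected on 1 of 3 virgin and 3 of 4 pregnant luminal arrays, so background also entered the values of these 5. The metabolic hormone gene Enho had 6.35, with 7.03 without virgin MaSC-enriched replicate 2, 5.60 without virgin MaSC-enriched replicate 3 and 6.95 without virgin luminal replicate 3. The Igf2 interaction was -5.19 without virgin luminal replicate 2. List medians of the interaction that passed were 1.79 for hormone-sensing markers, 1.14 for milk genes, 0.94 for luminal markers, 0.91 for interferon genes, 0.83 for skeletal muscle genes, -0.55 for lipid genes and -1.02 for Myc and ribosome genes. All 7 calls ended with an estimated correlation, with adjusted p = 0.344 for hormone-sensing, milk, luminal and lipid genes, 0.427 for interferon, 0.411 for muscle and 0.375 for Myc genes. The milk call also ended without the genes near the top of the scale (median 0.47, adjusted p = 0.421). Of 100 drawn assignments of pregnancy status within each population, 4 gave as many probes as the real one with its 1587, itself included, and the highest other gave 2582. The 3 others kept the status of every luminal array, so the luminal pregnancy difference entered their counts, and this test of no pregnancy effect at all did not decide on the interaction. The pregnancy difference common to both populations was then taken out of every array. Only 1 of the same 100 assignments, the real one, gave 1587 and the highest other gave 3, which argued against chance assignment of single arrays. Status was drawn apart for each population, although the pools described in the labels may have given both. Chance assignment of whole pools was therefore not tested.

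Chance splits of the arrays were argued against as the source of the count in 3 of the group comparisons. There the real split gave the most probes of 35, the smallest share that so many splits allow. The groups sat unevenly on the chips, so the splits did not separate group from chip. Of 35 splits of the MaSC-enriched arrays into groups of these sizes, only 1, the real one with 943 probes, gave as many, and the highest other gave 14. For luminal arrays the real split with 4087 probes was likewise 1 of 35, and the highest other gave 706. For the populations in pregnant mice the real split with 8260 was 1 of 35, and the highest other gave 0. For the populations in virgin mice the 10 splits were too few for a share under 0.05, and the real split gave 6095 and the highest other 474.

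Single arrays stood apart in 6 of 80 groups of values tested in the pregnant groups, where chance gives about 1 in 20. The RANK and NF-kB list mean was 9.45 in pregnant luminal replicate 4, with the others at 9.80 to 9.83. The dissociation stress list mean was 12.27 on the same array, with the others at 12.43 to 12.46. Wap was at 14.86 in pregnant luminal replicate 2, with the others at 14.56 to 14.59. The luminal marker list mean was 9.24 in pregnant MaSC-enriched replicate 2, with the others at 8.78 to 8.86. In pregnant MaSC-enriched replicate 1, Krt8 was at 13.68 with the others at 13.99 to 14.04, and Pgr, near background, at 5.75 with the others at 5.27 to 5.31.

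Of 18 milk genes, 12 were higher in pregnant MaSC-enriched cells, which may reflect their own expression or luminal cells in the sort. Chip alone was argued against, since 10 of the 12 risen genes passed with chip as a block, as was normalization, since at least 11 passed under each of the 5 other value settings. Among 5 risen genes below the top of the scale, luminal cells would need to make up a median of 11.2% (7.27% to 17.4%), and only 0.984% of 305 abundant luminal transcripts, or 3, lay below that share by more than 2 SE. These were Wfdc12 at 2.60%, Lao1 at 5.77% and Gldc at 6.19%, each below the lowest needed share. The shares reached (median 34.6%) include what MaSC-enriched cells express themselves, so the few below cannot show luminal cells to be the source. The fifth percentile of the shares reached was 9.82% in pregnant and 2.42% in virgin mice. Luminal cells as a source stayed open, with a sort purity above 90% in the labels. A biological response of the MaSC-enriched cells was untested beside them. For the 7 risen genes near the top of the scale a median share of 74.2% would be needed, but compression of the scale there kept this from deciding.

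Of 17 basal markers, 6 were higher in pregnant luminal cells, and basal cells in the luminal sort are a candidate source. The list call ended with an estimated correlation (adjusted p = 0.555), with array weights (adjusted p = 0.691) and with chip as a block (adjusted p = 0.0522), so only the single genes are weighed. For these genes chip was argued against, since 6 of 6 passed with chip as a block, and normalization for the most part, since at least 4 of 6 passed under each other value setting. A share of basal cells could not be decided, because a single risen gene, Tagln, was below the top of the scale. It needed 0.968%, and 0.262% of 381 abundant basal transcripts lay below that share by more than 2 SE. The other 5 needed a median of 6.22% (1.98% to 51.4%) near the top of the scale, with Krt14 at 51.4% and Acta2 at 35.1%. Krt5 reached 1.10% and Trp63 1.49% of their level in pregnant MaSC-enriched cells, and a biological change in luminal cells stayed untested.

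Of 10 hormone-sensing genes, 6 were lower in pregnant luminal cells, which a smaller share of hormone-sensing cells might explain. The list call ended with an estimated correlation (adjusted p = 0.0918). A smaller share cannot raise a gene, so it was argued against for Tnfsf11, which was higher by 3.68 (SE 0.35). For the genes that fell it stayed open, because genes chosen for their fall cannot decide. Of 4 above background in both states, 1, Esr1, lay over 2 SE from their median of -3.36. Of all 7 members above background in both states, 4 lay over 2 SE from that median. Beside Esr1 and Tnfsf11 these were Wnt4 (-0.84, SE 0.29) and Cxcl14 (0.64, SE 0.36). That median came from genes chosen for falling, so the distance of other members from it decided nothing about 1 common fall. Cxcl14 was also higher in MaSC-enriched than in luminal cells of virgin mice. Chip and normalization were argued against as well, since 6 of 6 fallen genes passed with chip as a block and 6 under each other value setting. A change in the cells themselves during pregnancy stayed open beside a lower cell share.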

How the results depend on the processing

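Alternatives were planned before the data were examined, except those for the correlation of pregnancy effects across genes and the lists without part of their genes, which were added after the data were seen. For the correlation, r ran from 0.29 to 0.391 between settings and from 0.29 to 0.412 without 1 array, against 0.377. Counts of probes past the threshold stayed within 1.5 times of the reported ones under each alternative background correction, normalization, filter, chip block and moderation. With array weights, which gave virgin MaSC-enriched replicates 2 and 3 weights of 0.318 and 0.254, the counts were 544 for pregnancy in MaSC-enriched cells, 9271 for pregnancy in luminal cells and 2700 for the interaction; the cause was not tested. With only the compared groups in the fit, the counts were 392 for pregnancy in MaSC-enriched cells and 3539 for the populations in virgin mice. In this setting they were 4188 for pregnancy in luminal cells and 10125 for the populations in pregnant mice. Both comparisons with lower counts held the virgin MaSC-enriched arrays, whose median SD was 0.44, against 0.24 to 0.29 in the other groups. Whether that spread or the smaller number of arrays lowered them was not tested. A minimum fold of 1.5, a stricter criterion by construction, gave 179 and 1343 for pregnancy in MaSC-enriched and luminal cells, 2778 and 3672 for the populations in virgin and pregnant mice, and 527 for the interaction. With replicate number as a block the 5 counts were 821, 3581, 6482, 8728 and 1878. This block ended the MaSC-enriched pregnancy calls of hormone-sensing (adjusted p = 0.0579) and leukocyte genes (adjusted p = 0.0574). It began those of milk genes in the luminal pregnancy comparison (adjusted p = 0.046) and of pericyte and skeletal muscle genes between the populations in virgin mice (each with adjusted p = 0.0338). Leaving out 1 array gave 497 (without pregnant MaSC-enriched replicate 2) to 2011 (without virgin MaSC-enriched replicate 2) for pregnancy in MaSC-enriched cells. The other ranges were 2836 to 4737 for pregnancy in luminal cells, 4767 to 6431 and 7064 to 9131 for the populations in virgin and pregnant mice, and 1077 (without virgin luminal replicate 1) to 2645 (without virgin MaSC-enriched replicate 2) for the interaction. Among named genes that passed in either of the fits compared, only the adipocyte hormone Adipoq turned direction, while values near 0 that passed in neither, such as Krt18 in the MaSC-enriched pregnancy comparison (0.02, with -0.24 without virgin MaSC-enriched replicate 1), were not counted. The Adipoq difference in MaSC-enriched pregnancy ran from -1.37 without virgin MaSC-enriched replicate 3 to 0.83 without replicate 2. Its interaction was 1.29 with chip as a fixed block and ran from -0.94 to 1.26 without those arrays; the cause was not tested. Of 575 named gene results, median scaling ended 26 calls and began 6, no filter ended 36 and began 3, chip as a fixed block ended 19 and began 40, array weights ended 21 and began 51, and the minimum fold ended 90. Of 115 list results, an estimated correlation ended 26 calls, and fry ended 3, those of proliferation, leukocyte and Myc genes in the MaSC-enriched pregnancy comparison, and began 17. Median scaling left 39.6% of probes past the threshold higher in the MaSC-enriched pregnancy comparison against 55.8%, 25.5% in luminal cells against 49.8%, 55.6% between the populations in pregnant mice against 46%, and 75% in the interaction against 62.7%. Cyclic loess gave 55.9% in pregnant mice, and 53.1% against 46.8% in virgin mice. The stricter filter left 538 of the named gene and 110 of the list results with a value. Signal over background, at 7.44 to 16.3 between the 90th and 10th percentile of raw intensity, limits values at the low end, and about log2 14 at the top, where milk and keratin genes lay, limits differences of the brightest genes.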

Other observations

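Genes named here for opposite directions, for a turned order of the populations or for virgin replicate 3 were chosen after their values were seen, while the gene lists were set before the data were examined.

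A small set of genes changed in opposite directions in the populations during pregnancy. There were 17 genes higher in MaSC-enriched and lower in luminal cells, against 34.8 if independent, and 11 the other way, against 28.6. Alcam, a cell adhesion molecule, rose by a log2 of 1.45 in MaSC-enriched and fell by 3.68 in luminal cells (interaction 5.13, SE 0.47, adjusted p = 1.14e-05), and Lmo7, a junction-associated protein, rose by 2.43 and fell below detection on every pregnant luminal array (adjusted p = 2.89e-06 for the interaction). Etv5, a transcription factor downstream of FGF signals, rose by 1.92 and fell by 0.90 (interaction 2.82, SE 0.40). The secreted Wnt antagonist Sfrp1 fell by 1.43 in MaSC-enriched and rose by 1.11 in luminal cells, and the urea cycle enzyme Ass1 fell by 1.71 and rose by 1.26. The order of the populations turned for 30 genes that were higher in MaSC-enriched cells in virgin mice and lower in pregnant ones, against 406 if independent, and for 56 the other way, against 381. Slpi went from 1.93 to -3.63 and the vitamin D receptor Vdr from 0.97 to -1.38, while the growth factor receptor Fgfr2 went from -1.37 to 3.45 and Wnt5a from -2.48 to 2.48.

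A few picked genes were highest on the virgin replicate 3 arrays of MaSC-enriched and luminal cells. Chac1, a glutathione-degrading enzyme, was at log2 12.85 and 12.49, with 4.94 to 9.47 on the other 12 arrays. Trib3, a target of the integrated stress response, was at 11.40 and 11.05, with 7.48 to 10.01 elsewhere, and the antioxidant gene Srxn1 at 14.11 and 13.10, with 6.57 to 11.82 elsewhere. The cystine transporter Slc7a11 was at 10.06 and 6.07 and the hormone Fgf21 at 10.56 and 5.52, so they stood out in MaSC-enriched replicate 3 alone. The stress gene Ddit3 was at 9.74 and 9.04, with 8.38 to 10.02 elsewhere, and the dissociation stress list mean of 12.04 in virgin MaSC-enriched replicate 3 was the lowest of the 14 arrays. These arrays shared chip 4 with pregnant MaSC-enriched and luminal replicates 4, where Chac1 was at 6.17 and 9.47.

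Lists not described so far were not called in the pregnancy comparisons. Of 11 prolactin and STAT genes, 1 rose in MaSC-enriched cells (median 0.15, mean 0.20, with the test's direction down, adjusted p = 0.953) and 2 fell in luminal cells (median -0.06, adjusted p = 0.863), the inhibitor Socs3 at -2.10 (-2.69 without virgin luminal replicate 3) and the kinase Jak2 at -1.14. The Jak2 call ended without virgin luminal replicate 1 (adjusted p = 0.122) or 3 (0.112), or pregnant luminal replicate 3 (0.0641) or 4 (0.0847). Of 14 secretory pathway and unfolded protein response genes, none passed limma's test in MaSC-enriched cells (median 0.05, 3 with an unadjusted p below 0.05) and Herpud1 fell by 0.88 in luminal cells (list median 0.11). Notch and interferon lists had medians of -0.44 and 0.06 in MaSC-enriched cells, with no call. The proteasome subunit Psmb8 was higher there by 1.34, a call that ended without virgin MaSC-enriched replicate 3 (adjusted p = 0.109) or pregnant MaSC-enriched replicates 2, 3 or 4 (0.0932, 0.0679 and 0.0592).

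Markers of cells that the sort was to remove or that it did not address were as follows. The endothelial, pericyte and fibroblast medians were -0.11, -0.23 and 0.39 in the MaSC-enriched pregnancy comparison and -0.03, -0.16 and 0.15 in the luminal one, none called. The pericyte list was called in the MaSC-enriched one without virgin MaSC-enriched replicate 3 (median -0.66, adjusted p = 0.00966). Of 3 adipocyte markers, Lep was higher in pregnant MaSC-enriched cells by 1.31 (adjusted p = 0.037, with 0.101 without virgin MaSC-enriched replicate 3). The adipocyte list (median 1.31) was called with chip as a block (1.60, adjusted p = 0.0158) and without virgin MaSC-enriched replicate 2 (1.66, adjusted p = 0.0252). In luminal cells Lpl, a lipase that adipocytes and mammary epithelium express, rose 8.94-fold, with a list median of -0.28 and mean of 0.82. Of 5 skeletal muscle genes, 2 rose in MaSC-enriched cells, and 1 rose and 2 fell in luminal cells, with list medians of 0.11 and -0.79. Adjusted over the list alone, 4 fell in luminal cells. Acta1 rose by 2.73 in MaSC-enriched cells, a call that ended without virgin MaSC-enriched replicate 3 (adjusted p = 0.0662), and fell by 2.71 in luminal cells (-3.31 without virgin luminal replicate 3). Mb rose by 1.19 in MaSC-enriched and 1.02 in luminal cells, calls that ended with median scaling (adjusted p = 0.105 and 0.183). The first also ended with array weights (adjusted p = 0.0569) or without virgin MaSC-enriched replicate 1 or 3 (0.0583 and 0.084) or pregnant MaSC-enriched replicate 2 or 4 (0.076 and 0.0623), and the luminal one without virgin luminal replicate 3 (0.0718). Tnnc2 fell in luminal cells, from log2 7.32 to 5.32. The luminal muscle list was called without virgin luminal replicate 3 (median -1.32, adjusted p = 0.0258). The erythroid genes Alas2 and Hba-a1 differed by 0.26 and 1.82 in MaSC-enriched and by 0.26 and -0.04 in luminal cells, and the Schwann cell genes Mbp and Sox10 by -1.21 and 0.62 and by -1.05 and 0.73, none past the threshold. Dissociation stress genes had medians of 0.15 and -0.28, with Hspb1 falling 4.36-fold in luminal cells (adjusted p = 5.7e-05). Housekeeping medians were -0.02 and -0.09 in the pregnancy comparisons and 0.01 and 0.06 between the populations of virgin and pregnant mice, with 0 of 8 genes past the threshold by limma in each of these and 0, 1, 2 and 0 with an unadjusted p below 0.05.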
